A study of Zea mays with 100 samples.

How the data were processed

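Leaf RNA of 26 inbred maize lines, the founders of the nested association mapping (NAM) population, was measured by RNA sequencing. The labels list 100 samples, 24 of paired-end and 76 of single-end libraries, all from leaf at the R1 (silking) stage of greenhouse plants. Seedlings had 16 h of light and 8 h of dark, and older plants had 12 h of light at 26 °C by day and 20 °C by night, per the labels' protocols. RNA was extracted with a column kit and libraries were made with a TruSeq mRNA protocol, per the labels' protocols. Nothing in the labels says that the libraries of a line came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

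The authors deposited 26 tables, one for each line, with TPM values (transcript abundance scaled to a fixed total in each library) for each listed transcript. Salmon 1.1.0, a tool that estimates transcript abundance from reads, is named in the submitters' processing notes. Its settings and the annotation release are not given in the sources used here. Each deposited TPM column summed to 1e+06, so TPM gives shares within a library and keeps no sequencing depth, and the depth of every library is unknown. Salmon shares reads among similar transcripts, so values of single isoforms and of near-identical gene copies are less certain than sums over a gene. TPM also rests on an effective transcript length, which depends on the fragment lengths known or assumed for a library, so paired-end and single-end libraries can differ for that reason.

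The tables hold 98 library columns, headed by codes that appear in no label. Each column was assigned to the line of its table and to no single sample. The codes begin with AK201 in 23 columns, AK244 in 72 and AK407 in 3, and the 3 AK407 columns are those of B73. In 25 lines the number of AK201 columns equals the number of paired-end samples, in 25 the number of AK244 and AK407 columns equals the number of single-end samples, and in 24 both hold. AK201 libraries are therefore presumed to be paired-end and the others single-end. This is a presumption from counts, and the code series could also differ in batch or in plants. Library numbers are the order of the columns and pair nothing. No 2 columns of a line were identical, and the number of columns left out was 0. CML277, P39 and Tzi8 have 2 AK244 columns and every other line but B73 has 3.

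Each table lists the line's own gene models and no identifier is shared between lines. The name table used here matched 0 of the 39092 B73 gene identifiers. For this reason the planned tests by shared identifier, the tests of genes for nucleotide-binding leucine-rich repeat receptors (NLRs) and the tests of 14 gene lists were not run, and NLR genes and gene lists are not analysed here. Identifiers are given as the tables have them, with no gene name. The rule for named genes, fixed before the data were examined, takes the 15 B73 genes of highest mean TPM, the transcript of highest mean TPM in every line, and from a contrast within a line at most 2 transcripts higher and 2 lower by the largest fold change.

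For each library, 3 measures were computed. The share expressed is the percent of listed transcripts at 1 TPM or more. The top-100 share is the percent of the TPM total held by the 100 highest transcripts. The isoform share is the mean percent of a gene's TPM held by its highest transcript, over genes with at least 2 listed transcripts and a summed value of at least 5 TPM. Lines were compared over the 75 AK244 and AK407 libraries by a permutation test of the one-way F statistic with 100000 relabellings, which is two-sided by construction. Every line has its own annotation, so a difference between lines in any of these measures holds both the plants and the annotation. The AK201 library was compared with the mean of the AK244 libraries of its line over the 23 lines that have both, by a two-sided permutation test of 100000 sign flips, with Benjamini-Hochberg adjustment over 3 measures. The smallest p that these permutations can give is 1e-05.

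Within each of the 23 lines, the AK201 library was tested against the AK244 libraries with limma 3.58.1 (eBayes with a trend) on log2(TPM + 1), for transcripts with a mean of at least 1 TPM, at a Benjamini-Hochberg threshold of 0.05. A fold change on this scale understates the change of low transcripts. The single AK201 library is assumed to vary like the AK244 libraries. The limma test was tested on simulated data with 50 changed transcripts for each of 4 fold sizes. For B97 (31235 transcripts), with the same noise for every transcript, it recovered 10% of 2-fold, 94% of 4-fold and 100% of 16-fold changes. With each transcript's own spread (31233 transcripts) it recovered 0% of 2-fold, 0% of 4-fold, 40% of 16-fold and 44% of 64-fold changes. For CML277, with 2 AK244 libraries, it recovered 20% of 2-fold and 100% of 4-fold changes with the same noise for every transcript (27160 transcripts), and 0% at 64-fold with each transcript's own spread (27135 transcripts). Counts of called transcripts can therefore miss many changes. Changed transcripts were drawn only from those with a higher AK244 mean, and a spread of 0 was replaced by the median spread. Transcripts listed at 0 in every AK244 library were thus never among the changed ones, so the simulation does not cover calls on them. The first form of this simulation, in which the noise was shuffled among transcripts, recovered none of the changed transcripts, and its noise and fold sizes were then altered while the test itself was kept.

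Alternatives fixed before the data were examined were thresholds of 0.1 and 5 TPM, the 10 and 1000 highest transcripts, isoform minimums of 1 and 20 TPM, sums over genes, a pseudocount of 0.1, no filter and a filter of 5 TPM, quantile normalization, and leaving out each library in turn. Robust fits, sums over genes with robust fits, a filter on transcripts above 0 in every library, genes with exactly 2 listed transcripts, other choices of the highest transcripts, and leaving out single lines or 1 M162W library were added after the data were seen. The comparisons of libraries by correlation, the relation between 2 measures, and the tests along the identifier order were also chosen after the data were seen. A comparison of lines grouped by where their highest transcript lies was computed and left out, because it grouped samples by a measured outcome. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and the R package data.table, version 1.17.8.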

Results

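Leaf transcript abundances of the 26 maize NAM founder lines were compared in 98 libraries. B73, Ky21 and NC358 had 3 libraries each, and the other 23 lines had 1 library of the AK201 code series, presumed paired-end, beside 2 or 3 libraries of the AK244 series, presumed single-end. The tables listed from 54411 transcripts in CML277 to 72640 in P39, and from 39092 genes in B73 to 41241 in Ki11. CML228 and CML277 listed fewer transcripts per gene, 1.36 in each table, against a median of 1.77 over the lines. Sequencing depth is unknown, because TPM keeps none.

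The first question was how much of each line's gene set was expressed in leaf. The mean share of listed genes at 1 TPM or more ran from 49.97% ± 0.19 (SD, n = 3) in CML322 to 55.7% ± 0.66 (SD, n = 3) in Ki11. B73 had 54.7% ± 0.75 (SD, n = 3), which is 21384 ± 295 genes (SD, n = 3), and CML322 had 20339 ± 78 genes (SD, n = 3). The share of genes listed at 0 in every library of a line had a median of 21.7%, from 15.1% in Ki11 to 26.6% in P39. A line with fewer libraries has fewer chances to show a gene above 0. B73, CML277, Ky21, NC358, P39 and Tzi8 had fewer libraries than the other lines, and B73, Ky21 and NC358 had none of the AK201 series. The highest shares were those of P39, B73, Ky21 and CML277, and NC358 and Tzi8 also lay above the median. The range therefore holds the number of libraries as well as the lines. Ki11 identifiers have a different form from those of the other lines.

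Counted by transcript, the mean share at 1 TPM or more ran from 40.8% ± 1.23 (SD, n = 3) in CML333 to 47.4% ± 0.96 (SD, n = 3) in CML228. The CML228 table lists 55808 transcripts and that of CML333 70552. In numbers the order of CML228 and CML333 is reversed, with 26453 ± 534 transcripts against 28754 ± 866 (SD, n = 3). Lines held 78.9% of the variance among libraries, against a mean of 33.8% after relabelling (permutation p = 1e-05, the smallest these permutations can give; 75 libraries). The pooled SD within lines was 1.11 percentage points. Without CML228 and CML277, whose tables list fewer transcripts, the lines held 68.7% (permutation p = 1e-05, 70 libraries). The highest mean was then 45.0% in Ki11. For shares of genes the lines held 81.1% of the variance (permutation p = 1e-05), with a pooled SD of 0.91 percentage points. The lines' TPM values rest on separate annotations, so these differences between lines hold both leaf expression and annotation.

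**Figure D1:**
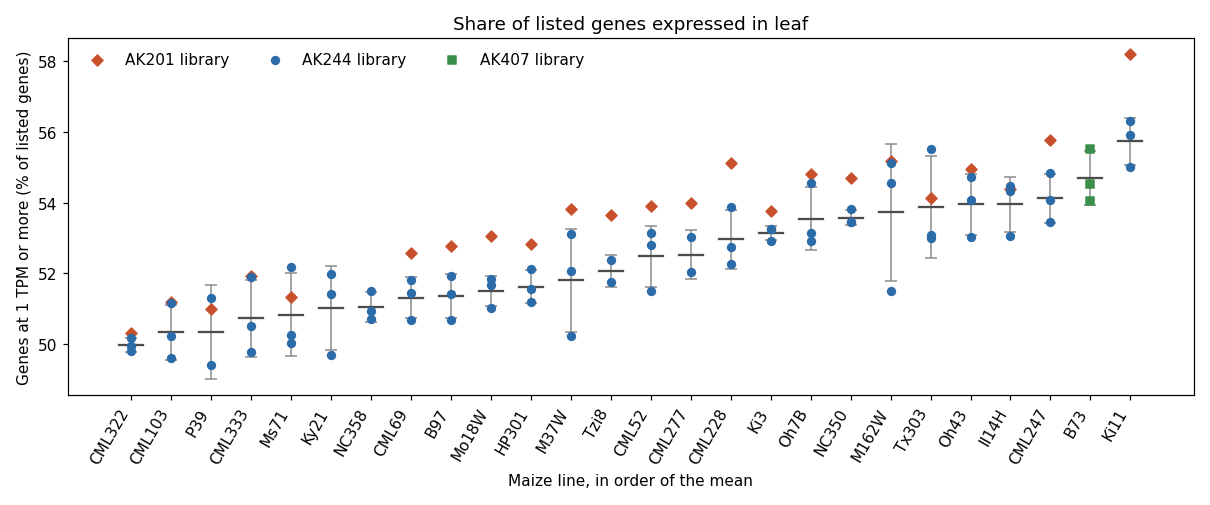
Percent of listed genes at 1 TPM or more (vertical axis) for each of the 26 lines (horizontal axis, in order of the mean). Points are single libraries by code series, horizontal bars are means of the AK244 or AK407 libraries, and whiskers are their SD; line means run from 49.97% in CML322 to 55.7% in Ki11, and the vertical axis does not start at 0.

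The second comparison asked how far leaf expression was concentrated in a few transcripts. The 100 highest transcripts held 22.3% ± 1.17 (SD, n = 3) of the TPM total in B73 and 37.4% ± 2.38 (SD, n = 3) in CML333. B97 with 37.2% ± 1.08 (SD, n = 3) and CML69 with 36.0% ± 1.86 (SD, n = 3) lay near the top, and Ki3 with 23.7% ± 0.86 (SD, n = 3) lay near the bottom. In B73, 872 ± 56 genes (SD, n = 3) made up 50% of the TPM total, while in B97 230 ± 29 genes (SD, n = 3) did. Lines held 80.9% of the variance of the top-100 share (permutation p = 1e-05, 75 libraries), with a pooled SD of 2.48 percentage points. B73 was the single line of the AK407 series, so its place cannot be separated from that series. M162W library 1 stood apart from the other libraries of its line, with a top-100 share of 28.9% against 21.1% and 20.5%, and without it M162W rather than B73 had the lowest mean, 20.8%.

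**Figure D2:**
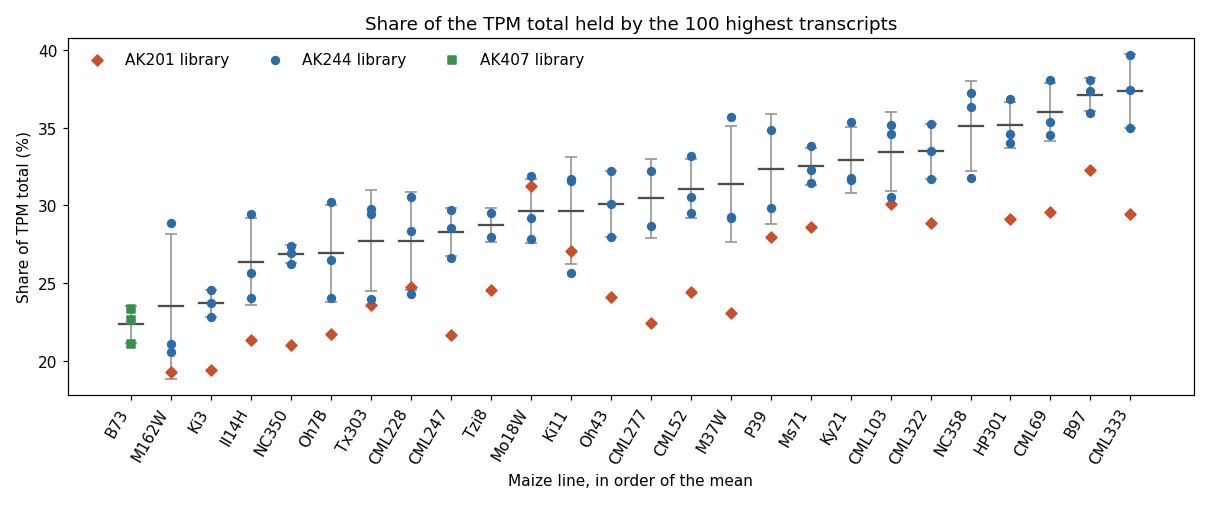
Percent of the TPM total held by the 100 highest transcripts (vertical axis) in each library of the 26 lines (horizontal axis, in order of the mean). Points are libraries by code series, horizontal bars are means of the AK244 or AK407 libraries and whiskers their SD; AK201 libraries lie below the mean in 22 of 23 lines, Mo18W being the exception, and the vertical axis does not start at 0.

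The highest transcript of a line differed widely in level. Zm00026ab165880_T001 reached 57980 ± 2902 TPM (SD, n = 3) in CML333, Zm00036ab169340_T001 54407 ± 6212 TPM (SD, n = 3) in NC350 and Zm00020ab166210_T001 40386 ± 3140 TPM (SD, n = 3) in CML69. Zm00037ab165380_T001 reached 37910 ± 7228 TPM (SD, n = 3) in NC358. At the other end, the highest M162W transcript, Zm00033ab340450_T001, had 9167 ± 6815 TPM (SD, n = 3), and the highest CML228 transcript, Zm00022ab326840_T004, had 11914 ± 2313 TPM (SD, n = 3). The highest transcripts of M37W, 27897 ± 15677 TPM (SD, n = 3), and Ki11, 15540 ± 10430 TPM (SD, n = 3), varied greatly between libraries of the same line. These levels come from tables with separate annotations and were not tested between lines.

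**Figure D3:**
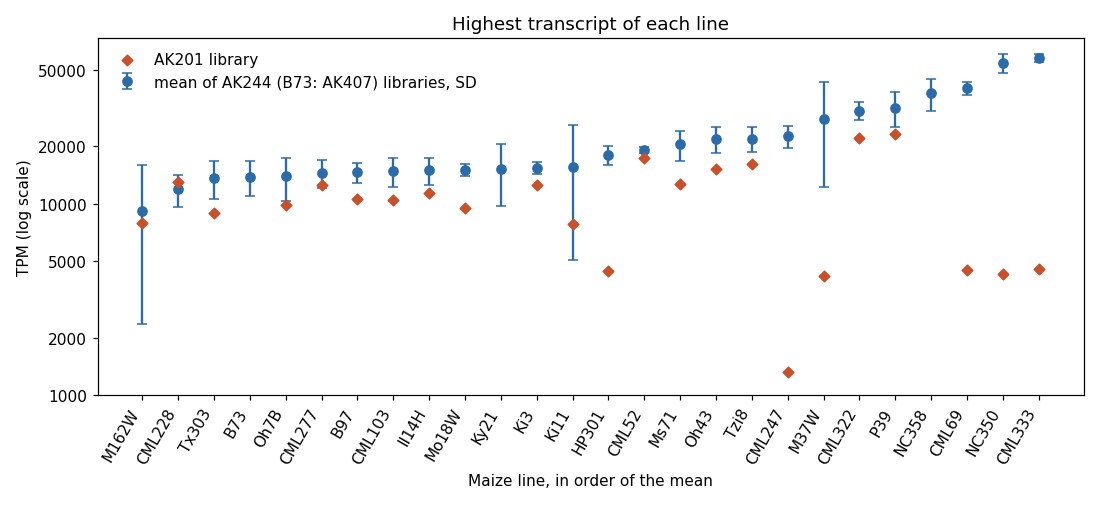
Level in TPM (vertical axis, log scale) of the transcript with the highest mean in each of the 26 lines (horizontal axis, in order of the mean). Circles and whiskers are the mean and SD of the AK244 libraries (AK407 in B73), and diamonds are the AK201 library of the 23 lines that have one; the mean runs from 9167 TPM in M162W to 57980 TPM in CML333, where the AK201 library had 4573 TPM.

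In B73, the reference line of maize genomics, the most abundant gene was Zm00001eb032690 with 13872 ± 2834 TPM (SD, n = 3). Zm00001eb320890 followed with 9296 ± 353 TPM and Zm00001eb164610 with 9174 ± 655 TPM (SD, n = 3). The difference between the latter pair was smaller than the spread of either. Zm00001eb262520 had 8443 ± 4044 TPM, Zm00001eb365040 7429 ± 236 TPM, Zm00001eb171230 6650 ± 456 TPM and Zm00001eb362480 6278 ± 171 TPM (SD, n = 3). The next were Zm00001eb123780 with 5726 ± 259 TPM, Zm00001eb020690 with 5216 ± 453 TPM, Zm00001eb415460 with 5076 ± 911 TPM and Zm00001eb198420 with 4991 ± 666 TPM (SD, n = 3). Zm00001eb299990 had 4598 ± 451 TPM, Zm00001eb435850 4528 ± 2209 TPM, Zm00001eb262130 3587 ± 1824 TPM and Zm00001eb436560 3410 ± 1773 TPM (SD, n = 3). The tables and the name table used here do not pair these identifiers with names.

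The third comparison concerned the use of isoforms. In multi-transcript genes at 5 TPM or more, the highest transcript held on average 76.7% ± 0.49 (SD, n = 3) of the gene's TPM in Oh7B and 83.6% ± 1.28 (SD, n = 2) in CML277. CML228 had 82.4% ± 0.19 (SD, n = 3), B73 80.8% ± 1.03 (SD, n = 3) and CML247 79.2% ± 1.02 (SD, n = 3), and the median of the line means was 77.4%. Lines held 91.8% of the variance (permutation p = 1e-05, 75 libraries), with a pooled SD of 0.58 percentage points. Without B73, CML228 and CML277 the lines held 59.7% (permutation p = 0.0013, 67 libraries), where relabelling gave a mean of 33.4%.

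**Figure D4:**
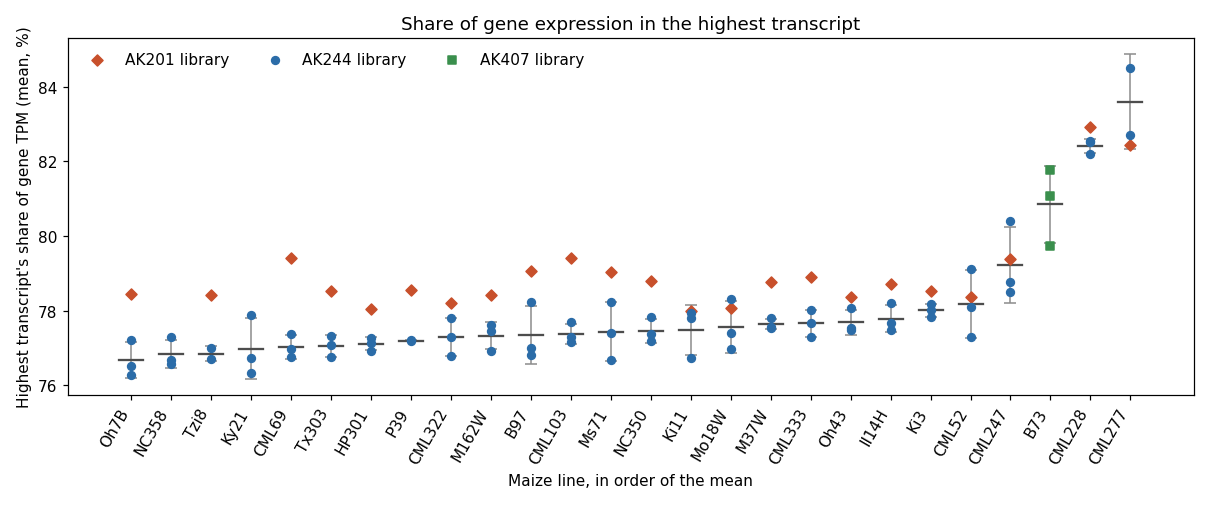
Mean percent of a gene's TPM held by its highest transcript (vertical axis), over genes with 2 or more listed transcripts and at least 5 TPM, for the 26 lines (horizontal axis, in order of the mean). Points are libraries by code series, bars and whiskers are the mean and SD of the AK244 or AK407 libraries; B73, CML228 and CML277 lie above the other lines, and the vertical axis does not start at 0.

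AK201 and AK244 libraries of the same line were then compared, which addresses whether the presumed library layouts give the same picture. A larger share of transcripts reached 1 TPM in the AK201 library of all 23 lines, 46.1% against 42.9% on average. The mean difference was 3.13 percentage points with an SD of 0.73 over lines (permutation adjusted p = 1e-05). After summing to genes it was 1.21 percentage points with an SD of 0.58 (permutation p = 1e-05). The 100 highest transcripts held less of the total in AK201, 25.5% against 30.4%, lower in 22 of 23 lines (mean difference -4.97 percentage points, SD 2.13, permutation adjusted p = 1e-05). In Mo18W the AK201 value was 31.3% and the AK244 mean 29.7% ± 2.07 (SD, n = 3). The isoform share was higher in AK201 in 22 of 23 lines, by 1.01 percentage points on average (SD 0.75, permutation adjusted p = 1e-05). In CML277 it was lower. With a minimum of 1 TPM instead of 5 TPM the difference was 0.44 percentage points (SD 0.95, permutation p = 0.038), higher in 15 lines and lower in 8. Layout, batch and plants cannot be separated in this contrast.

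The transcript with the highest AK244 mean was lower in AK201 in 21 of 23 lines on the log2 scale, CML228 and M162W being the exceptions, and over 4-fold lower in TPM in 6. A fall is favoured by this choice, since the transcript was picked for a high AK244 value. The transcript highest in AK201 was lower there than in AK244 in 13 of 23 lines on the log2 scale and over 4-fold lower in TPM in 0. Where the transcript highest in 2 AK244 libraries was set against the third AK244 library, it was over 4-fold lower in 2 of 60 comparisons, and against AK201 in 18 of 60. These were 3 comparisons in each of 20 lines that share libraries and reuse the 1 AK201 library, so they are not independent. Both of the 2 were in M162W, and the 18 came from CML247, CML333, CML69, HP301, M162W, M37W and NC350. In CML333, Zm00026ab165880_T001 had 4573 TPM in AK201, a log2 difference of -3.66 (limma SE 0.30, adjusted p = 0.021). In CML69, Zm00020ab166210_T001 had 4486 TPM, a log2 difference of -3.17 (limma SE 0.37, adjusted p = 0.041). Neither call held with 1 AK244 library left out, which leaves a fit with 2 AK244 libraries. In the simulation of such a fit for CML277, 0% of 64-fold changes were recovered with each transcript's own spread. With the same noise for every transcript, 100% of 4-fold changes were recovered. Whether the calls were lost through the smaller fit was therefore not settled. Without library 1, 2 and 3 the log2 difference was -3.63, -3.70 and -3.66 in CML333. In CML69 it was -3.12, -3.16 and -3.23. CML333 and CML69 were the 2 lines whose highest transcript passed the threshold with all libraries. Values for the other 4 lines did not pass it: 22507 against 1321 TPM in CML247 (limma adjusted p = 0.15), 17969 against 4462 TPM in HP301 (limma adjusted p = 0.090), 27897 against 4193 TPM in M37W (limma adjusted p = 0.33) and 54407 against 4284 TPM in NC350 (limma adjusted p = 0.39). Of the 100 highest transcripts of each line, the number lower in AK201 depended on how they were chosen. It had a median of 71 when they were chosen in AK244, 60 when chosen in the mean of both series and 46 when chosen in AK201. With transcripts chosen in 2 AK244 libraries, the mean number lower than in those libraries was 70.1 in AK201 and 52.8 in the third AK244 library over 20 lines, more in AK201 in 19 of them (difference 17.3, SD 7.78, two-sided permutation p = 1e-05). These ways of choosing were added after the data were seen.

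Over all tested transcripts, a median of 1447 per line were called between AK201 and AK244 (limma adjusted p under 0.05), 4.69% of those tested. The calls rest on an assumed spread, since the AK201 arm is 1 library. A count depends on the spread among the AK244 libraries as well as on the difference, so it does not rank lines by difference. The median SD of log2 gene values was 0.123 in Ki3 and 0.366 in M162W, which had fewer calls. Not every line went this way, as Oh7B had more calls than HP301 with a larger SD, 0.218 against 0.160. The Pearson correlation of AK201 with AK244 in Ki3, 0.919, was above the mean of 0.904 over lines. Ki3 had the most, 4726. CML277 and P39 had 0, where limma gave 6784 and 5983 transcripts at an unadjusted p under 0.05 and quantile normalization with limma called 57 and 0. Other limma settings called more in these lines, up to 2010 and 5617 without a filter, and 1488 and 3807 for transcripts above 0 in every library. Summed over lines, 22400 calls were higher and 20881 lower in AK201. Of the higher calls, 43.0% were listed at 0 in every AK244 library, and of the lower calls 31.7% were listed at 0 in AK201. The former passed the filter through the AK201 value alone and had no spread between AK244 libraries. The median log2 difference of all tested transcripts was 0.20 over lines and 0.06 after quantile normalization, which called 42.9% of its transcripts higher against 51.8% without it. With any 1 of 3 AK244 libraries left out, the median over 20 lines fell to 0 calls, with 7940, 6182 and 7102 transcripts at an unadjusted limma p under 0.05 without library 1, 2 and 3.

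**Figure D5:**
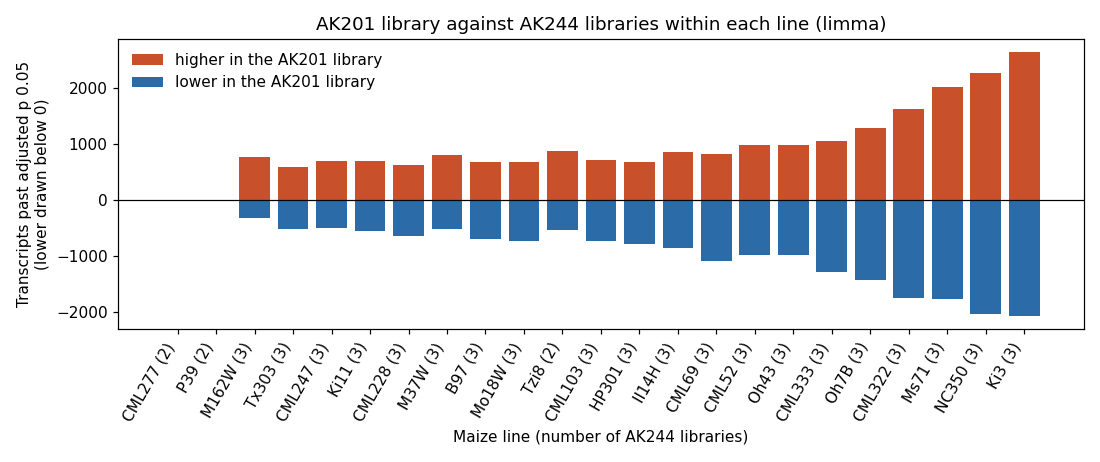
Number of transcripts past a limma adjusted p of 0.05 (vertical axis, lower calls drawn below 0) between the AK201 library and the AK244 libraries in each of 23 lines (horizontal axis, with the number of AK244 libraries in parentheses). The number depends on the spread among the AK244 libraries of a line as well as on the difference. Bars start at 0; Ki3 has the most calls, 4726 in all, and CML277 and P39 have 0.

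Genes with several listed transcripts held a median of 80.8% of the higher and 81.0% of the lower calls, against 69.2% of the tested transcripts, and both shares exceeded the tested share in all 21 lines with calls. Of the 42 transcripts with the largest rises, a pair per line, 32 belonged to multi-transcript genes, and the sum over the gene lay within 2-fold of the AK244 level for 29. In Mo18W, Zm00034ab034690_T003 had 8610 TPM in AK201 and was listed at 0 in the 3 AK244 libraries (limma adjusted p = 0.017), while its gene had 8973 TPM in AK201 and 8381 ± 1215 TPM (SD, n = 3) in AK244. In NC350, Zm00036ab033550_T003 had 9301 TPM in AK201 against 0.733 ± 1.27 TPM (SD, n = 3; limma adjusted p = 0.013), and its gene had 14072 TPM against 8441 ± 782 TPM (SD, n = 3). Of the 42 transcripts with the largest falls, 24 belonged to multi-transcript genes, a smaller share than among the tested transcripts. The sum over the gene lay within 2-fold for 14. In CML228, Zm00022ab453010_T001 had 4932 ± 871 TPM in AK244 (SD, n = 3) and was listed at 0 in AK201 (limma adjusted p = 0.012), and it was the single transcript of its gene. In CML333, Zm00026ab258460_T001, also single, had 4251 ± 687 TPM in AK244 (SD, n = 3) and was listed at 0 in AK201 (limma adjusted p = 0.0091). With any 1 AK244 library left out, the calls named for CML228, CML333 and Mo18W did not hold. In NC350 limma made calls only without library 2. The simulation of a fit with 2 AK244 libraries, for CML277, recovered 0% of 64-fold changes with each transcript's own spread. With the same noise for every transcript it recovered 100% of 4-fold changes. Of the lines with 2 AK244 libraries, Tzi8 had 1424 calls, and CML277 and P39 had 0. Whether these calls were lost through the smaller fit was therefore not settled. Summed to genes, a median of 359 genes per line were called. Of the gene calls of all lines together, 62.7% were higher. Ki3 and Ms71 had the most gene calls, and in both more were higher. In B97, CML103, CML247, CML277, CML69, HP301, Il14H and P39 more genes were lower than higher.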

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

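The test of the AK407 series and the test of listed transcripts in AK201 libraries were chosen after the values were seen; the tests of isoform assignment and of listed transcripts in AK244 and AK407 libraries were set before theirs were. In lines with 4 libraries, 60 sets of 4 values were screened for a library far from the other 3. Were the code series alike, chance alone would single out about 1 in 20. A total of 5 stood out, and 4 of them were AK201 libraries with a higher share of transcripts at 1 TPM or more. These shares were 44.4% in HP301 against at most 41.6% in AK244, 47.4% in Ki3 against at most 44.0%, 45.4% in Mo18W against at most 42.2%, and 47.2% in NC350 against at most 44.3%. The AK201 share lay above every AK244 library in all 23 lines, so these 4 lines are not exceptions. Their differences from the AK244 mean ran from 3.02 to 3.81 percentage points, against 3.13 on average over lines. Their AK244 SDs were small, from 0.24 to 0.35, while CML247, with a difference of 4.51, was not singled out. In Ki11, AK244 library 3 had an isoform share of 76.7% while the other 3 libraries lay between 77.8% and 78.0%. In CML277 the isoform share in AK201 minus AK244 was -1.15 percentage points, below both AK244 libraries, whereas the AK201 library lay above every AK244 library in 19 lines. This difference between CML277 and the other lines was not tested.

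The lower top-100 share of AK201 libraries (mean difference -4.97 percentage points, permutation adjusted p = 1e-05, lower in 22 of 23 lines) was weighed against 1 technical explanation. Reads assigned to other isoforms of the same genes would lose the difference on summing, but 101% of it was left after summing to genes. Differences in depth, which is unknown, and in layout, effective length, batch or plants between the code series remain open and were not tested, and the design names no biological factor between the series.

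The higher isoform share of CML228 and CML277 could come from the few transcripts their tables list per gene, 1.36 in each. Over genes with exactly 2 listed transcripts, an excess was left in the AK244 libraries of CML228 and CML277, whose mean was 88.0%. CML228 had 87.7% ± 0.06 (SD, n = 3) and CML277 88.4% ± 0.89 (SD, n = 2), against 85.4% to 86.4% in the other 23 AK244 lines. By the rule set before this value was seen, though after the data were first seen, this counts against the number listed as the whole cause. These genes need not be the same in each table, however. On average they were 3373 of 5708 multi-transcript genes at 5 TPM or more in CML228 and 3396 of 8460 in B97. A gene with 2 transcripts listed in CML228 may have more listed in other tables, so this comparison cannot exclude the number listed. In the AK201 libraries no excess was left, with a mean of 87.7% (87.9% and 87.5%) inside the 86.9% to 88.0% of the other 21 lines, while over all multi-transcript genes they had 82.9% and 82.4% against 78.0% to 79.4%. B73, whose isoform share was also higher, listed the most transcripts per gene of the 26 lines, 1.84. Over genes with exactly 2 it still had 87.3% ± 0.87 (SD, n = 3), above the AK244 range by slightly more than its SD. By the rule, likewise set before this value but after the data were first seen, this counts against the number listed as the whole cause in B73. The same limit on the genes compared holds. The 87.3% lies inside the AK201 range, so this reading rests on AK244 as the reference, taken because the B73 samples are single-end by their labels. With 0 other lines in the AK407 series, its code series and the line cannot be told apart. The number of transcripts listed remains open. Which isoforms a table lists, the sequencing depth, which is unknown, and a difference between the lines themselves remain open and untested.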

How the results depend on the processing

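No paired analysis was possible because the deposited columns carry no replicate numbers; this holds for pairing by replicate number, while AK201 and AK244 were compared within lines. Other settings listed in advance for the tests by shared identifier, of NLR genes and of gene lists were not run, as those tests were not run. Robust fits, the filter on values above 0, exactly 2 listed transcripts and leaving out lines or M162W library 1 were chosen after seeing the data. The differences between lines stayed past the threshold under all alternatives run: 11 for the share expressed, 8 for the top-100 share and 10 for the isoform share. The AK201 minus AK244 differences kept their sign and side of the threshold under all 8, 8 and 7 alternatives; the isoform difference was smallest with a minimum of 1 TPM (0.44 percentage points, permutation p = 0.038). The median count of called transcripts per line, 1447, was within 1.5 times under 5 alternatives, but single lines moved far under them: robust fits took Tzi8 from 1424 to 0 and M162W from 1091 to 108, and the filter on values above 0 took M162W to 0, P39 from 0 to 3807 and Tzi8 to 6289, above the 5950 of Ki3. It rose to 7243 without a filter on low values, where more transcripts were tested and 82.5% of calls were higher in AK201. It fell to 359 after summing to genes and 576 with a robust fit on genes. Over all lines together 62.7% and 65.4% of these gene calls were higher, though not in every line. The cause was not tested. With a pseudocount of 0.1, 41.1% of calls were higher, with a filter of 5 TPM 41.1%, and with robust fits 43.3%, against 51.8%. Leaving out each AK244 library in turn gave medians from 0 to 0 over 20 lines, with fewer samples in each fit, and up to 2002 calls in NC350 without library 2. For CML277, P39 and Tzi8 this leaves 1 library against 1, with no residual degrees of freedom, and was not run. Depth is unknown, so no limit from depth can be given.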

Other observations

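The tests of this part were chosen after the data were seen, and the prediction for the correlation along the identifier order was set before its result. Over 23 lines, the mean Pearson correlation across genes was 0.954 within AK244 (SD 0.022) and 0.904 between AK201 and AK244 (SD 0.015), lower across series in 23 of 23 lines (permutation p = 1e-05, the smallest possible). The highest transcript of a multi-transcript gene differed between 2 libraries for 11.05% of genes within AK244 (SD 1.83) and for 20.8% across series (SD 1.96), higher in 23 of 23 lines (permutation p = 1e-05). Genes are not independent replicates, so these correlations describe libraries. M162W library 1 had correlations of 0.850 and 0.855 with the other AK244 libraries of its line, which had 0.914 with each other, and 0.875 with the AK201 library, higher than with either AK244 library.

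Lines with a larger top-100 share had a smaller share of genes at 1 TPM or more. Over 26 lines, Pearson's r was -0.742 (permutation p = 5e-05) and Spearman's rho -0.781 (permutation p = 2e-05), for the 1 relation computed, so that adjusted and raw p are equal. Without the 2 lines farthest from the median r was -0.693, and without B73, the single AK407 line, it was -0.710. Among AK244 libraries as deviations from their line mean r was -0.682, and among the 23 AK201 libraries it was -0.573. TPM sums to a fixed total, so a gain of the highest transcripts lowers all others, and part of this relation follows from the unit.

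Leaf expression was weakly correlated between genes next to each other in the identifier order of their table. The Spearman correlation across genes between neighbours had a median of 0.145 over the 26 lines, from 0.118 to 0.154, and 0.071 at a distance of 2 genes and 0.011 at a distance of 100. Among 100 shuffled orders the largest absolute value had a median of 0.013. The correlation at a distance of 100 was 7.54% of that at a distance of 1. This argues against a broad trend along the numbering as the main source of the correlation between neighbours. A weak broad trend is not excluded. In Oh43 the correlation at 100 was 0.018 against a shuffled maximum of 0.014, though in most lines it lay below that maximum. Local duplicates that share reads may add to the correlation between neighbours and were not tested.

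The highest transcripts of many lines, though not of all, lay at similar places of the identifier order. Of 325 pairs of lines, 76 had places within 1% of the gene order of each other, where random placement gave a mean of 6.47 and at most 29 (permutation p = 1e-05). In CML69 the place was 37.2%, in CML333 37.5%, in NC350 37.6%, in Ki3 83.0% and in P39 83.3%. In 5 lines no other line lay within 1%: B73 at 7.46%, CML52 at 27.7%, M37W at 47.25%, Ki11 at 67.7% and CML228 at 70.6%. A candidate explanation is that the transcripts belong to matching genes of several lines, a hypothesis on which sequence was not used here; the place alone does not show that they are the same gene.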
